A study of Rattus norvegicus with 24 samples.

How the data were processed

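Messenger RNA was measured on 24 Affymetrix rat expression arrays. Per the labels, each array was hybridised with RNA pooled from 5 male rats, stored in RNAlater and purified with QIAzol and RNeasy columns, so that each array is 1 pool and n counts pools. Pools were treated as independent, also between structures, although the same rats could have given several structures. The deposited values are intensity, a linear probe set signal, and GCOS 1.2 is named in the submitters' processing notes. Its parameters and detection calls are not given in the sources used here. On each of the 24 arrays the deposited intensity had a 2% trimmed mean of about 100, which is what scaling each array by 1 factor gives, and no log or quantile step had been applied. The smallest value in the table was 0.00259.

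The table held 31099 probe sets. The 57 control probe sets were left out of the tests, which left 31042. Gene names were taken from the annotation table of the array: 20826 probe sets carried 1 gene, 436 carried several and 9780 carried none, and the named ones covered 14217 genes. Probe sets with several genes or none were kept in the counts of probe sets and left out of the counts of genes. No genome coordinates are printed because the annotation of the probe sets names no build.

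The samples were grouped by strain and structure as the labels give them: 5 arrays of the neurointermediate lobe of the pituitary (NIL), 5 of the paraventricular nucleus (PVN), 4 of the supraoptic nucleus (SON) and 5 of the rostral ventrolateral medulla (RVLM) from SHR rats, and 5 of the RVLM from WKY rats. Arrays were numbered by their titles, with an unnumbered title taken as number 1. WKY arrays of the other structures were not analysed here.

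Intensities were log2-transformed with no pseudocount, and each array was shifted so that its median equalled the mean of the array medians. Probe sets were kept when their mean log2 value over the arrays of a fit lay above the 40th percentile, which left 18625 in each fit. Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with an intensity trend, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. The strain comparison used the 10 RVLM arrays. The 3 structure comparisons used all 19 SHR arrays: PVN minus SON, NIL minus the mean of PVN and SON, and RVLM minus the mean of PVN and SON. The last 2 share their reference arrays and were not compared with each other. A gene was represented by its probe set with the highest mean. SE is the standard error of the log2 difference from the moderated fit. Means and SDs of groups are of the deposited intensity.

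The genes to be named were set by a rule written before the data were examined. For the strain comparison these were, among called genes whose groups did not overlap and whose symbol was not a placeholder, the 10 largest rises and the 10 largest falls. Th, Dbh, Pnmt, Agtr1a, Nos1, Cd36 and Ephx2 were always included, together with at most 3 called members of each gene list. For the structure comparisons these were, again among called genes whose groups did not overlap, the 5 largest rises and falls, and at most 4 called members of each list. Genes named outside the rule are said to have been chosen after their values were seen. The gene lists, 27 for the strain comparison and 19 for the structures, were also written before the data were examined. Each list with at least 3 tested members was tested with camera of limma at a preset correlation between genes of 0.01, two-sided, with p adjusted over the lists of a comparison. The test was repeated with an estimated correlation. List members were counted when called over all genes and when adjusted over the list alone. The list of genes with a reported SHR strain difference comes from general knowledge of other tissues.

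The alternatives were values as deposited, quantile normalization, a pseudocount of 16 or 64, no filter, a filter at the 60th percentile, eBayes without an intensity trend, arrayWeights, the replicate number as a block, each array left out in turn, genes as the mean of their kept probe sets, and other arrays in the fit. Leaving out each array in the list tests, and giving each count that used the PVN without the array labelled PVN replicate 3, were added after the data had been seen. The strain and the PVN against SON fits were tested on simulated data of the same size. Of the changes of 1 on the log2 scale, 87.9% and 84.8% were called. Of those of 0.5, 29.9% and 31.8% were called, and 4 and 8 unchanged probe sets were called. The simulation changed far fewer probe sets than the real PVN against SON fit called (2740), and its noise was independent between probe sets. The shares therefore do not carry over to that fit, and false calls under correlated noise were not tested. Other splits of the arrays into groups of the same sizes were fitted 100 times per comparison. An array was set apart from its group by Dixon's test at the 95% level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

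Structure cannot be separated from the day or batch of processing, because the labels give neither. The geometric mean intensity of the hybridisation controls was 465 in NIL, 387 in PVN, 504 in SON, 810 in SHR RVLM and 782 in WKY RVLM arrays. Signal over background was not computed, because background values were not used here.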

Results

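Gene expression was profiled in 4 structures of the rat brain and pituitary that take part in the control of blood pressure and body fluid. The arrays came from the spontaneously hypertensive rat (SHR) and the Wistar-Kyoto rat (WKY), the strain with normal blood pressure that serves as its control. The PVN and SON of the hypothalamus hold the neurons that make vasopressin and oxytocin, the NIL holds the nerve endings that release both hormones together with the melanotrophs of the intermediate lobe, and the RVLM drives sympathetic outflow to blood vessels. SHR rats gave 5 NIL, 5 PVN, 4 SON and 5 RVLM arrays, and WKY rats gave 5 RVLM arrays. The median intensity of an array lay between 35.9 and 46.5. Spearman correlations of an array with its own group were 0.956 to 0.966 in NIL, 0.912 to 0.955 in PVN, 0.964 to 0.970 in SON, 0.956 to 0.967 in SHR RVLM and 0.963 to 0.969 in WKY RVLM. The lowest, 0.912, belonged to the array labelled PVN replicate 3 (PVN array 3), which correlated at 0.936 with the SON arrays, so counts that use the PVN are also given without it. The number of arrays limits the precision of each value.

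The first comparison asked which genes differed between the hypertensive and the normotensive strain in the RVLM. The genes with the largest differences were not those of transmitter systems. Ephx2, the soluble epoxide hydrolase that degrades vasodilator epoxides of arachidonic acid, had an intensity of 118 ± 14.9 (SD, n = 5) in SHR and 13.0 ± 8.25 in WKY. This was a rise of 3.50 on the log2 scale (SE 0.417, adjusted p = 8.82e-05). Its values in WKY, 3.12 to 21.1, lay under the median intensity of every array, so the size of the rise is loosely determined. The peroxisomal membrane protein gene Pxmp4 rose by 2.38 (SE 0.141, adjusted p = 2.45e-08), from 30.2 ± 6.42 in WKY to 158 ± 13.2 in SHR, and its other probe set differed in the same direction. The thiosulfate sulfurtransferase-like gene Tstd1 had the largest fall, −2.60 (SE 0.231, adjusted p = 2.86e-06), with 26.1 ± 9.64 in SHR and 148 ± 26.0 in WKY. By contrast the genes of adrenaline-making neurons, a hallmark of this region, did not pass the test: Th had a difference of −0.02 (SE 0.126, adjusted p = 0.978), Pnmt of 0.06 (SE 0.205, adjusted p = 0.955) and Dbh of 0.15 (SE 0.190, adjusted p = 0.860).

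Of 18625 probe sets, 295 were called by limma, 136 higher and 159 lower in SHR, and 75 of them differed by at least 1 on the log2 scale. Over genes, 147 of 10415 were called (1.41%), 54 higher and 93 lower. The balance of probe sets turned with values as deposited (167 higher and 163 lower), with all 24 arrays in the fit (118 and 96) and without WKY RVLM array 4 (110 and 105) or 5 (129 and 108). That of genes did not turn, with 73 higher and 96 lower, 53 and 56, 47 and 56, and 50 and 61 in these settings. The other genes with the largest rises were RT1-CE16 (2.34), Zfp597 (1.65), Fry (1.64), Septin5 (1.34), Chi3l1 (1.19), Actr8 (1.18), Rrs1-ps9 (1.12) and Adpgk (1.11). Fry, a large protein that organises cell polarity and microtubules, had intensities of 566 ± 59.7 and 178 ± 18.8 (SD, n = 5 each). The falls after Tstd1 were Grifin (−2.02), Prss35 (−1.76), Cidea (−1.39), Ncaph (−1.37), Setd1b (−1.35), Hmces (−1.34), Maip1 (−1.25), Elavl1 (−1.24) and Mylk (−1.22). Mylk, the kinase of smooth muscle myosin light chain, had 144 ± 22.2 in SHR and 326 ± 27.1 in WKY. Cidea, a lipid droplet protein, had 35.8 ± 6.33 and 91.1 ± 6.74. Grifin (adjusted p = 0.0313) was no longer called without SHR RVLM array 1 or WKY RVLM array 2, 3, 4 or 5, with adjusted p of 0.0692 to 0.108, nor was Setd1b (adjusted p = 0.0124) without WKY RVLM array 4, with adjusted p = 0.0501. Elavl1 lost its call when a gene was taken as the mean of its kept probe sets and when all 24 arrays were fitted together.

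**Figure D1:**
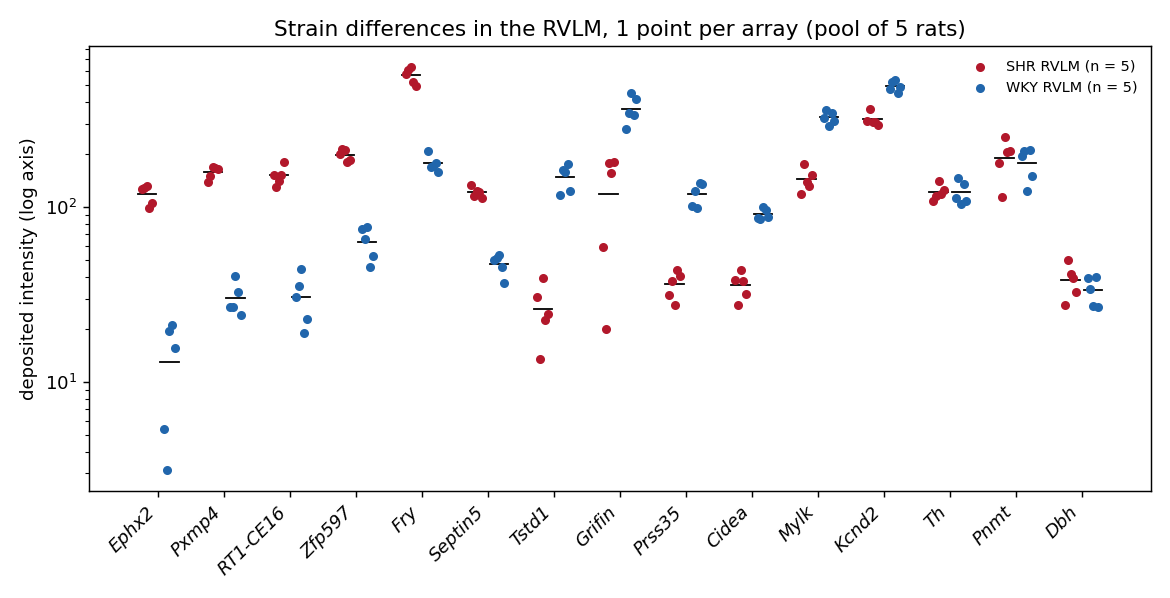
Deposited intensity (log axis) of 15 genes on the 5 SHR and 5 WKY RVLM arrays, with 1 point per array and a short line at each group mean. Ephx2 had means of 118 in SHR and 13.0 in WKY and Tstd1 of 26.1 and 148, while Th had 122 in both strains.

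Of the gene lists, antigen presentation held the most calls. Of 16 tested genes of antigen presentation, 2 rose (RT1-CE16, and the immunoproteasome subunit Psmb8 by 0.64), 3 fell (RT1-CE5 at −1.20, RT1-DMb at −0.61 and RT1-DMa at −0.52, the last 2 named after their values were seen) and 11 did not pass. Adjusted over the list alone, 3 rose and 4 fell, with RT1-A3 and RT1-CE10 added, also named after their values were seen. RT1 class I genes are close relatives of one another, so their probes can read related transcripts. The list as a whole was not called (mean −0.02, camera adjusted p = 0.874). Of 13 cytokine and adhesion genes, Il18 rose by 0.71 (adjusted p = 0.00830, 71.1 ± 6.08 against 43.1 ± 7.71) and the rest did not pass. The 20 interferon response genes and the 14 microglial genes held 0 called members.

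Of 12 genes of nitric oxide and cGMP signalling, Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, rose by 0.56 (adjusted p = 0.00448, 173 ± 13.5 against 114 ± 8.12). This call ended with the mean of the kept probe sets and with all 24 arrays in the fit. Adjusted over the list alone, Qdpr (−0.39) also fell, named after its value was seen. Of 6 renin-angiotensin genes, Agtrap, which promotes internalisation of the angiotensin receptor, rose by 0.93 (adjusted p = 0.0307), and leaving out any array but SHR RVLM array 4 or WKY RVLM array 2 ended that call (adjusted p 0.0501 to 0.101). The 4 adrenergic receptor genes and the 24 oxidant and antioxidant genes held 0 called members. Agtr1a and Nos1 lay under the filter, with 14.7 ± 2.15 and 15.9 ± 6.84 in SHR and 15.6 ± 4.27 and 20.1 ± 8.39 in WKY. So did Cd36, with 5.71 ± 2.95 and 5.10 ± 2.51. Of the genes with a reported SHR difference in other tissues, 2 were tested, Ephx2, which rose, and Gstm1 (0.32), which did not pass. Of 17 glutathione transferases and epoxide hydrolases, Ephx2 alone passed over all genes. Adjusted over that list, Gstt3 and Gstm1 rose as well, and Gstt2, Gstm4 and Gstm7 fell, all 5 named after their values were seen. The mean of that list was 0.08 and its median −0.18.

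Of 28 potassium, sodium and calcium channel genes, Kcnd2, which carries the A-type potassium current, fell by 0.67 (adjusted p = 0.000145, 317 ± 28.1 against 492 ± 35.2). Of 18 GABA and glycine genes, the GABA-degrading enzyme gene Abat fell by 0.39 (adjusted p = 0.0392), a call that ended without any array but SHR RVLM array 2 or 3 (adjusted p 0.0691 to 0.117). Called members numbered 0 in the lists of 5 catecholamine, 4 serotonin, 17 glutamate, 23 neuropeptide and 7 cholinergic genes. The glutamate list had camera adjusted p = 0.146, which became 0.0444 without SHR RVLM array 3 and 0.0342 without WKY RVLM array 5, while 0 lists were called in either case with an estimated correlation. Among cell type markers, Ttr of the choroid plexus fell by 1.11 (adjusted p = 0.0485), and leaving out any array but SHR RVLM array 4 or WKY RVLM array 1 gave adjusted p of 0.0643 to 0.132. The lists of 13 astrocyte, 15 oligodendrocyte, 17 endothelial and 16 pan-neuronal markers, of 14 immediate early genes and of 21 heat shock genes held 0 called members. Of 2 tested red blood cell genes 0 were called. Over all probe sets the limma test gave 1801 at an unadjusted p under 0.05. Adjusted over the list alone, counts differed from those over all genes only in the lists for which this is stated.

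Of 25 lists tested, 2 were called, both lower in SHR. The 43 respiratory chain genes had a mean difference of −0.16 (camera adjusted p = 0.00345) and the 24 ribosomal protein genes of −0.19 (camera adjusted p = 0.0171), while 0 members of either list passed alone. With an estimated correlation each had adjusted p = 0.926. Without SHR RVLM array 2 the means were −0.01 in both lists, with adjusted p = 0.943 and 0.970, and without WKY RVLM array 2 adjusted p was 0.0805 and 0.232. The other 23 tested lists had camera adjusted p of 0.146 to 0.911.

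The next comparison, within SHR, set the PVN against the SON, 2 nuclei that share vasopressin and oxytocin neurons but differ in their other cells. The shared hormones were bright in both: Avp had 4453 ± 522 (SD, n = 5) in PVN and 5056 ± 495 (n = 4) in SON, and Oxt had 4118 ± 667 and 4513 ± 343, and neither passed the test (log2 differences −0.16 and −0.11, both named after their values were seen). Avp at 5284 on PVN array 4 and 4200 on PVN array 5 lay at or near the highest intensity of those arrays (5284 and 4227). Differences between values so near the top may be understated, so an equal level in both nuclei is not shown. The PVN had higher releasing hormones of its small neurons. Crh, which drives the adrenal stress axis, had 354 ± 183 against 17.4 ± 2.35 (log2 difference 3.96, limma adjusted p = 0.000569), and Trh, which drives the thyroid axis, had 777 ± 394 against 64 ± 17.3 (3.37, adjusted p = 0.000116). The SON had higher genes of meninges and connective tissue, such as Ptgds, the prostaglandin D synthase of the leptomeninges, with 1232 ± 1967 in PVN and 5622 ± 709 in SON (−3.24, adjusted p = 0.000428).

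In all 2740 of 18625 probe sets were called, 1522 higher and 1218 lower in PVN. The balance turned under other settings, with 1684 higher and 1826 lower with values as deposited, 2183 and 2435 with arrayWeights, and 999 and 1167 without PVN array 1, against 1709 and 893 without PVN array 4. Over genes 1711 of 10598 were called, 956 higher and 755 lower. With PVN array 3 left out the counts were 3905 probe sets, 1985 higher and 1920 lower, and 2440 genes. On that array Crh was 38.1 (393 to 514 on the other PVN arrays), Trh 138 (762 to 1183), Pmch 259 (2304 to 3736) and Ptgds 4749 (231 to 451), while its Avp and Oxt lay with those of the other PVN arrays. Without it some differences were larger in size, such as 4.65 for Crh, 3.90 for Trh, 5.51 for Pmch, 4.06 for Hcrt, 4.6 for Sst, −4.01 for Ptgds, −4.53 for Col1a2, −4.01 for Ogn, −4.07 for Lum and −2.74 for Slc5a7. Counts also depended on SON array 3, without which 1616 probe sets and 1007 genes were called. Of 17 tested lists 6 were called, and 9 without the array labelled PVN replicate 3. With all arrays and an estimated correlation 2 were called.

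Among 8 parvocellular genes of the PVN, 6 rose and 2 did not pass (camera adjusted p = 5.55e-06, and adjusted p = 0.0432 with an estimated correlation). Beside Crh and Trh these were somatostatin (Sst, 3.77, 2200 ± 1180 against 115 ± 27.2), the opioid precursor Penk (1.69), Ntng1 (1.19) and the glucocorticoid receptor gene Nr3c1 (0.31). Ntng1 and Nr3c1 were named after their values were seen. Without the array labelled PVN replicate 3 the count was 6 as well. Of 7 genes of neighbouring hypothalamic and forebrain cells 4 rose, 3 without the array labelled PVN replicate 3, when Npvf lay under the filter and 1 gene fell, led by the melanin-concentrating hormone gene Pmch (4.81, 2581 ± 1403 against 69.9 ± 14.5) and the orexin gene Hcrt (3.42, 375 ± 284 against 25.4 ± 7.02), both made by neurons of the lateral hypothalamus. The others were Npvf (2.01) and Tcf7l2 (0.81). Npvf (adjusted p = 0.0423) passed the filter in 4 of 9 fits with an array left out, those without 1 SON array. It lost its call in each of them (adjusted p 0.0726 to 0.0996) and lay under the filter without any 1 PVN array. Adjusted over the list alone, Prkcd (−0.52), named after its value was seen, fell as well. That list had camera adjusted p = 0.0306, and adjusted p = 0.121 with an estimated correlation. It was no longer called without PVN array 1, 4 or 5 (adjusted p 0.0522 to 0.179), with quantile normalization or with a filter at the 60th percentile, and Tcf7l2 lost its call when a gene was the mean of its kept probe sets.

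Of 16 GABA and glycine genes 9 rose, among them Gabbr2 (1.32, 632 ± 96.2 against 257 ± 16.5), the vesicular transporter Slc32a1 (1.21) and the GABA-making enzyme Gad1 (1.04, 1218 ± 319 against 612 ± 216), and the receptor subunit Gabrb2 fell by 0.54, named after its value was seen. With PVN array 3 left out, 7 rose and 1 fell. The list had camera adjusted p = 0.000622, and adjusted p = 0.142 with an estimated correlation (0.289 without that array). Of 15 glutamate genes the receptor subunits Grik1 (1.02), Gria2 (0.80) and Grik4 (0.75) rose and 12 genes did not pass. Without that array 4 rose, and over the list alone, with all arrays, 9 rose (camera adjusted p = 0.000974, and adjusted p = 0.0238 with an estimated correlation). Of 16 pan-neuronal markers 4 rose, among them Rbfox3 (1.18) and the growth-associated Gap43 (1.03), and the list was not called (adjusted p = 0.367). These became 4 rises and 1 fall without PVN array 3.

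Of 11 choroid plexus and meningeal markers 9 fell in PVN, with Col1a2 (−3.36), the extracellular matrix proteoglycan Lum (−3.27, 85.1 ± 140 against 396 ± 128) and Ogn (−3.11) beside Ptgds, and Folr1 (1.12) rose, named after its value was seen. The list had camera adjusted p = 3e-06 and adjusted p = 0.17 with an estimated correlation. Without the array labelled PVN replicate 3, on which Lum was 336 (19.9 to 25.0 on the other PVN arrays), these became 3.06e-15 and 0.0126, again with 9 falls and 1 rise. Of 14 microglia and macrophage markers 3 fell: Fcgr2b (−1.26), Mrc1 (−1.18) and Ptprc (−0.72). Mrc1 (adjusted p = 0.0222) lost its call without PVN array 1 or 5 or SON array 1 or 3 (adjusted p 0.0570 to 0.0665), and Ptprc (adjusted p = 0.0457) without any array but PVN array 3 (0.0606 to 0.124). Over the list alone 5 microglial genes fell, C1qb (−0.51) and Laptm5 (−0.44) among them, named after their values were seen. Its camera adjusted p was 0.0306, and adjusted p = 0.776 with an estimated correlation, and the call ended without PVN array 4 or 5 or SON array 1 or 2 (adjusted p 0.0567 to 0.103) and with values as deposited or a filter at the 60th percentile. Without PVN array 3, 4 microglial genes fell and 1 rose. Of 12 astrocyte markers 4 fell, among them Aldh1l1 (−2.02, 187 ± 123 against 687 ± 62.3), the filament gene Gfap (−1.11) and the water channel Aqp4 (−0.62), while the growth factor receptor Fgfr3 (0.41, named after its value was seen) rose. The fall of the fourth, Gjb6 (−1.26, adjusted p = 0.0312), ended without PVN array 2, 4 or 5 or SON array 1 or 3 (adjusted p 0.0746 to 0.118). Col1a2 and Aqp4 lost their calls when the PVN and SON arrays were fitted alone. The astrocyte list was not called (adjusted p = 0.367). Over the list alone Slc1a3 (0.31), named after its value was seen, rose too.

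Of 13 magnocellular genes the opioid precursor Pdyn (−1.64, 809 ± 392 against 2397 ± 260) and Giot1 (−1.86) fell and the secretogranin Scg2 (1.23) rose. Leaving out PVN array 3 gave 4 rises and 2 falls. This list was not called (adjusted p = 0.781), and Cck (0.56), named after its value was seen, rose when adjusted over the list alone. Of 4 catecholamine genes Th fell by 1.01 (243 ± 91.0 against 476 ± 54.9), and Ddc (0.94) and Gch1 (0.79) rose, and without PVN array 3 these counts were 1 and 3. Gch1 (adjusted p = 0.0436) lost its call without any array but PVN array 3 (adjusted p 0.0639 to 0.113). Slc18a2 (0.49), named after its value was seen, passed when adjusted over the list alone. The catecholamine list had adjusted p = 0.367, which was 0.0460 without the array labelled PVN replicate 3, and then 0.308 with an estimated correlation. Among 6 cholinergic genes Chat (−2.67, adjusted p = 0.0246) and Slc5a7 (−1.98, adjusted p = 0.0425) fell and Isl1 (1.17, adjusted p = 0.0228) rose. The counts became 1 fall and 2 rises without PVN array 3. Chat was 148 on that array (1.82 to 16.9 on the other PVN arrays) and lay under the filter without it, and its PVN mean was then 8.89. It passed the filter in 4 of 9 fits with an array left out and lost its call in 2 of them, without PVN array 4 or 5 (adjusted p = 0.0619). Slc5a7 lost its call without any array but PVN array 3 (0.0678 to 0.115), and Isl1 without PVN array 2 or SON array 1, 3 or 4 (0.0518 to 0.0685). Prph (0.69), named after its value was seen, passed over the list alone. The list had adjusted p = 0.781.

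Further lists held few calls between the nuclei. Of 14 oligodendrocyte markers and 3 red blood cell genes 0 were called by limma, with adjusted p = 0.526 and 0.503 for the lists, where 5335 of all probe sets had an unadjusted p under 0.05. With PVN array 3 left out the oligodendrocyte list was called lower in PVN (5 genes lower, adjusted p = 0.0281, and adjusted p = 0.382 with an estimated correlation), as was the list of 17 endothelial and mural markers (adjusted p = 0.0281, against 0.342 with it, and adjusted p = 0.382 with an estimated correlation). Of those endothelial markers the glucose transporter Slc2a1 (0.75) rose and Slco1a4 (−0.68) fell, a call that ended when the PVN and SON arrays were fitted alone. Without PVN array 3, 1 endothelial marker rose and 5 fell, and 2 red blood cell genes fell. In the lists for the pituitary, Pam (−0.49) fell, and Trhr (0.69) and Col25a1 (0.58) rose, with adjusted p = 0.971 for 7 melanotroph, 0.526 for 7 anterior pituitary and 0.971 for 8 pituicyte genes. Without PVN array 3 these lists had 1, 2 and 1 rises and 1, 0 and 2 falls. Col25a1 (adjusted p = 0.0125) lost its call without SON array 1 (adjusted p = 0.0576). Gata2 and Hoxb3, the 1 tested member each of the serotonin and Hox lists, did not pass. Outside the lists, the largest falls among genes whose groups did not overlap were the chemokine Ccl5 (−2.76), Ifi27l2b (−2.54) and the apelin receptor Aplnr (−2.49), beside Ecrg4 (−2.61) and Cryba4 (−2.39). In these lists and those above, counts adjusted over the list alone were as over all genes except where stated.

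**Figure D2:**
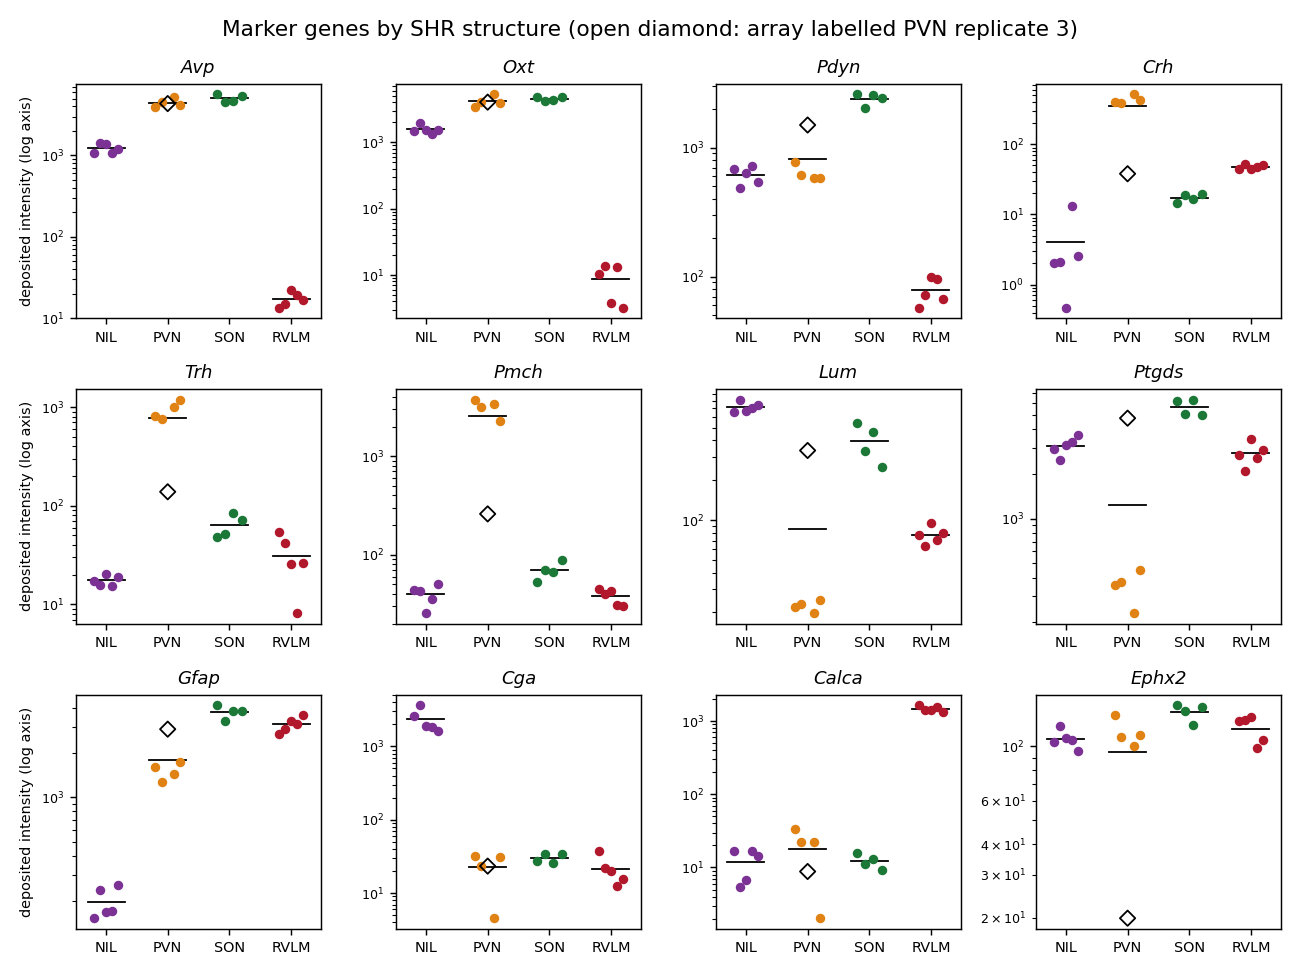
Deposited intensity (log axis) of 12 genes on the SHR arrays of NIL, PVN, SON and RVLM, with 1 point per array, lines at the group means and an open diamond for the array labelled PVN replicate 3. Avp had means of 4453 in PVN and 5056 in SON and 17.3 in RVLM, and Ptgds on the open diamond was 4749 against 231 to 451 on the other PVN arrays.

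The NIL was then set against the mean of PVN and SON, that is, the site of hormone release against the nuclei that supply it. The NIL had high pituitary transcripts and low transcripts of neurons, astrocytes and oligodendrocytes. The dopamine receptor Drd2, through which the hypothalamus restrains melanotrophs, had 1170 ± 136 (SD, n = 5) in NIL, 47.8 ± 25.8 in PVN and 39.4 ± 7.63 (n = 4) in SON (log2 difference 4.79, adjusted p = 4.26e-14). The inhibitory neuron gene Gad1 had 6.57 ± 2.56 in NIL against 1218 ± 319 and 612 ± 216 (−7.11, adjusted p = 3.31e-17). The NIL nevertheless held transcripts of the hormones that its axons carry, with 1226 ± 175 for Avp and 1568 ± 240 for Oxt, lower than in the nuclei by log2 differences of −1.98 and −1.49, named after their values were seen. Avp lay near the highest intensity of some PVN arrays, so its fall may be understated.

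By limma 10612 of 18625 probe sets were called, 5555 higher and 5057 lower in NIL, and 6248 of 10598 genes, 3270 higher and 2978 lower. Without the array labelled PVN replicate 3 these were 11243 probe sets, 5921 higher and 5322 lower, and 6572 genes. Of 17 tested lists 12 were called, and 13 without that array. With all arrays and an estimated correlation 6 were called. Among genes whose groups did not overlap, the largest rise was that of the anterior pituitary gene Gh1 (6.99, 693 to 6068 over the NIL arrays). The next among such genes were the epithelial adhesion gene Epcam (6.63, 1243 ± 111 in NIL), the anterior pituitary gene Cga (6.51), Adh1c (6.23) and the cardiac myosin gene Myh6 (6.02, 967 ± 184). The largest falls among such genes were the angiotensin precursor gene Agt, made by astrocytes in brain (−8.18, 9.90 ± 6.83 against 2227 ± 224 in PVN and 2467 ± 291 in SON), Gad1, Itih3 (−7.09), Mobp (−7.04) and D430041D05Rikl (−6.09). The low side of each of these falls lay under the median intensity of every array (3.10 to 24.5 in NIL), as did that of most of the rises, so their sizes and order are loosely determined.

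Of 7 melanotroph genes 5 rose. Beside Drd2 these were the transcription factor Tbx19 (3.62, 511 ± 76.7 in NIL), the prohormone convertase Pcsk2 (3.03), Chgb (2.08) and Scg5 (0.25), while the amidating enzyme Pam fell by 0.39, the last 2 named after their values were seen. Of 7 anterior pituitary genes 5 rose: growth hormone (Gh1), the common subunit Cga (2326 ± 821), Tshb (4.30, 699 ± 1055, with 2577 on NIL array 2 and 52.9 to 334 on the others), Lhb (2.49) and Fshb (2.20), while Trhr fell by 1.61, the last 2 named after their values were seen. Of 8 pituicyte genes 5 rose, with Lhx2 (2.55, 521 ± 31.1), Hes1 (1.61), Nkx2-1 (1.51), Col25a1 (1.45) and Tgfb2 (0.73), and Sox3 (−0.63) and Cldn11 (−0.56) fell, the last 3 named after their values were seen. Camera adjusted p was 0.00306, 0.0195 and 0.0254 for these lists, and adjusted p = 0.105, 0.148 and 0.100 with an estimated correlation. A filter at the 60th percentile also ended the calls of the anterior pituitary list and of the parvocellular list. Over the list alone Vim (−0.47) also fell among pituicyte genes, named after its value was seen.

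Neuronal, astrocyte and oligodendrocyte lists fell. Of 16 pan-neuronal markers 15 fell, among them Stmn2 (−3.49), Tubb3 (−3.34) and Nefm (−3.14), with camera adjusted p = 6.47e-10. All 12 astrocyte markers fell, such as Gfap (−3.75, 196 ± 45.7 in NIL) and Aldh1l1 (−4.37), as did all 14 oligodendrocyte markers, such as the myelin gene Mbp (−5.59, 52.7 ± 10.7 against 2235 ± 545 and 2746 ± 63.7). Camera gave these lists adjusted p = 2.13e-09 and 5.42e-08, and adjusted p = 0.0563 and 0.0873 with an estimated correlation. Of 16 GABA and glycine genes 13 fell (3.77e-09), and Gabre (0.39), named after its value was seen, rose over the list alone. Of 15 glutamate genes 10 fell, including the vesicular transporter Slc17a6 (−3.74), and the kainate receptor subunits Grik4 (1.23), Grik1 (0.99) and Grik2 (0.32) rose, named after their values were seen (0.000714). Cholinergic genes, 4 of 6, fell as well (0.00481), with the receptor gene Ret at −6.03 and Chat at −4.13. The last 3 lists and the pan-neuronal list kept their calls with an estimated correlation (adjusted p = 0.0143, 0.0143, 0.0367 and 0.0333). With PVN array 3 left out the falls in these 6 lists numbered 15, 12, 14, 13, 11 and 3 in the order given. The astrocyte and oligodendrocyte lists were then called with an estimated correlation (adjusted p = 0.0431 and 0.0262) and the cholinergic list was not (0.0540).

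Hypothalamic peptide lists fell too. Of 13 magnocellular genes 10 fell, with Vgf (−4.83), Cartpt (−4.27) and Gal (−4.03) ahead of Avp and Oxt, and Giot1 (1.31) and Scg2 (0.82) rose, named after their values were seen. The list had adjusted p = 5.12e-05, and adjusted p = 0.0143 with an estimated correlation. Of 8 parvocellular genes 7 fell, with Crh at −4.89 and Sst at −4.39, and Penk rose by 0.94, named after its value was seen (adjusted p = 0.00536, and adjusted p = 0.105 with an estimated correlation). Of 7 genes of neighbouring cells 4 fell, Calb2 (−4.97), Pmch (−3.25), Hcrt (−2.59) and Lef1 (−2.09), with adjusted p = 0.00790, and adjusted p = 0.0375 with an estimated correlation.

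Lists of vessels, blood and coverings were not called. Of 17 endothelial and mural markers 5 rose, with Ocln and Kdr (1.89 each), Eng (0.84), Pecam1 (0.49) and Flt1 (0.46), and 5 fell, with the barrier genes Cldn5 (−3.79) and Abcb1a (−3.76), Vwf (−3.39), Slco1a4 (−2.67) and Slc2a1 (−0.64). Those beyond the 4 largest in size were named after their values were seen, and the list had adjusted p = 0.367. Of 3 red blood cell genes Hbb (2.14, 3646 ± 719 in NIL) and Alas2 (1.95) rose (list adjusted p = 0.139). Of 11 choroid plexus and meningeal markers Dcn (3.00, 1157 ± 144 in NIL), Lum (2.54), Mgp (2.52), Col3a1 (1.89) and Col1a2 (1.60) rose and Ttr (−2.14), Igf2 (−1.69) and Folr1 (−1.17) fell, the last 2, Col3a1 and Col1a2 named after their values were seen. Ogn (1.13), named likewise, rose over the list alone. This list had adjusted p = 0.270, and 0.0151 without the array labelled PVN replicate 3, when 8 of its genes rose and 3 fell and adjusted p was 0.269 with an estimated correlation. Of 14 microglial markers 6 rose and 2 fell, Mrc1 (−1.12) and P2ry12 (−0.88), with complement C1qb (0.84) among those that rose (list adjusted p = 0.270). Of 4 catecholamine genes Gch1 (1.33) rose and Th (−3.77), Slc18a2 (−1.12) and Ddc (−0.39) fell (list adjusted p = 0.198). Ddc (adjusted p = 0.0395) lost its call without 1 of 8 arrays (adjusted p 0.0578 to 0.120: NIL array 1, 3 or 4, PVN array 1, 2 or 5, or SON array 1 or 4). In the list of serotonin neurons Gata2, a transcription factor of thyrotrophs and gonadotrophs as well, rose by 0.76 and Hoxb3 did not pass. Without PVN array 3 the rises became 8 in the microglial, 6 in the endothelial and 6 in the melanotroph list, and the other lists kept their counts except as stated. Counts adjusted over the list alone equalled those over all genes in every list of this comparison but the 3 named.

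**Figure D3:**
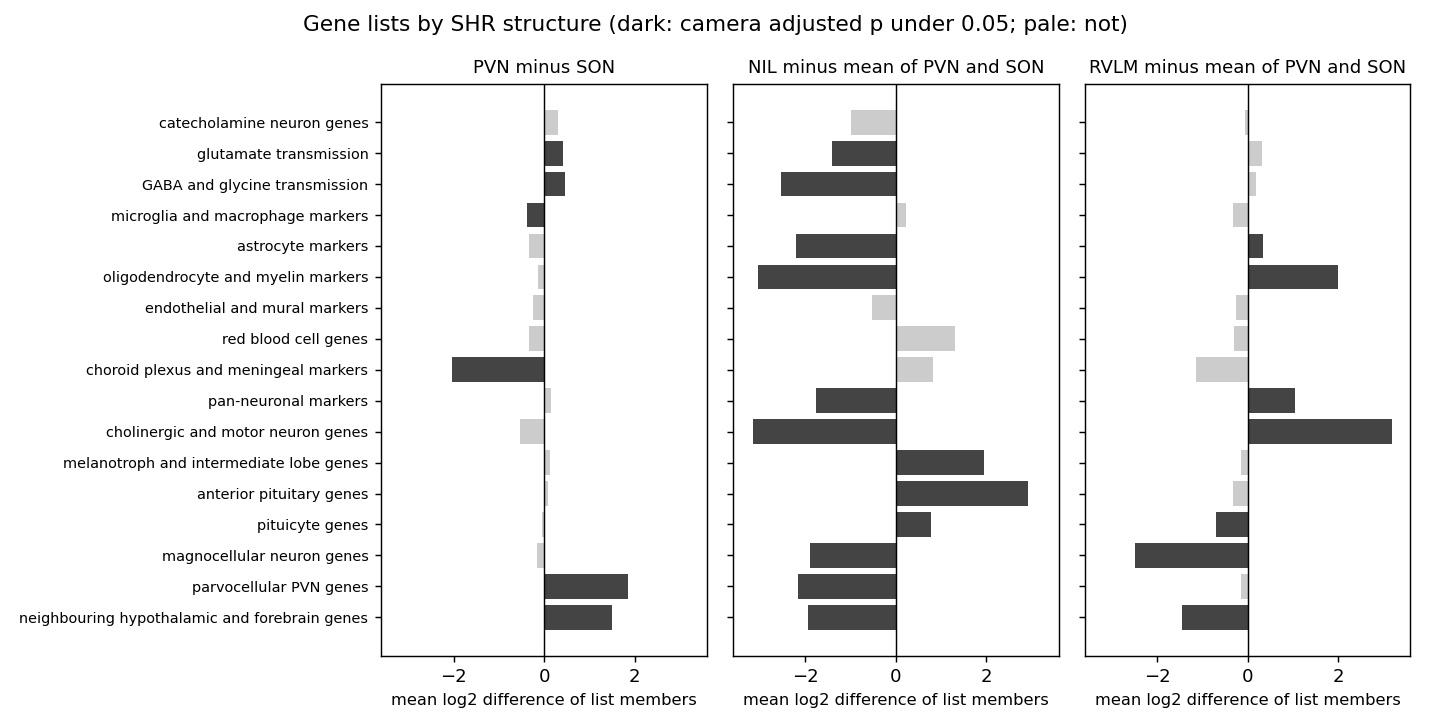
Mean log2 difference of the members of each gene list in the 3 structure comparisons, with dark bars for lists whose camera adjusted p was under 0.05. Of 17 tested lists 6 were called for PVN against SON, 12 for NIL and 7 for RVLM against the hypothalamic nuclei. With an estimated correlation these counts were 2, 6 and 2.

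Last, the RVLM of SHR was set against the mean of PVN and SON, a hindbrain vasomotor region against the hypothalamic nuclei. The RVLM had low oxytocin and vasopressin transcripts: Oxt had 8.86 ± 5.06 (SD, n = 5) against 4118 ± 667 in PVN and 4513 ± 343 in SON (log2 difference −9.10, adjusted p = 3.88e-17), and Avp had 17.3 ± 3.45 (−8.05, adjusted p = 2.21e-22). It had higher transcripts of cholinergic and motor neurons. Calca, the gene of calcitonin gene-related peptide, had 1475 ± 125 against 17.8 ± 12.5 and 12.4 ± 2.79 (6.97, adjusted p = 7.95e-11). The heavy neurofilament gene Nefh, a pan-neuronal marker, had 3560 ± 678 against 277 ± 88.9 and 271 ± 37.8 (3.78, adjusted p = 1.03e-12).

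By limma 9264 of 18625 probe sets were called, 4417 higher and 4847 lower in RVLM, and 5356 of 10598 genes, 2245 higher and 3111 lower. With values as deposited 4088 probe sets were higher and 5954 lower, and without PVN array 1 these were 4760 and 4709. Without the array labelled PVN replicate 3 these were 9924 probe sets, 4731 higher and 5193 lower, and 5674 genes. Of 17 tested lists 7 were called, with that array and without it. With all arrays and an estimated correlation 2 were called. After Calca the largest rises among genes whose groups did not overlap were the secreted phosphoprotein gene Spp1 (5.00, 768 ± 132 in RVLM), Lamp5 (4.47), Chodl (4.42) and Slc5a7 (4.15). After Oxt and Avp the largest falls among such genes were Cemip (−4.23), Coch (−4.14) and Pdyn (−4.06). The low side of the 4 falls before Pdyn and of Calca lay under the median intensity of every array. So did Spp1 in PVN (9.50 to 23.0), and the sizes and order of these differences are loosely determined.

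Of 14 oligodendrocyte markers 13 rose, among them Ugt8, which makes myelin galactolipids (3.73, 817 ± 78.7 against 59.0 ± 7.02 and 71.6 ± 13.0), Ermn (3.09), Mog (2.96) and Mobp (2.65). Over the list alone Pdgfra (−0.55), a marker of precursor cells, fell, named after its value was seen. Of 16 pan-neuronal markers 11 rose, with Nefm (3.58, 5923 ± 519), Nefl (2.32) and Snap25 (1.08) beside Nefh, and Elavl4 (−0.23) fell. Elavl4 was named after its value was seen, as was Gap43 (0.30), which passed over the list alone. Camera gave adjusted p = 5.11e-09 and 1.2e-07, and adjusted p = 0.0876 and 0.0865 with an estimated correlation. With PVN array 3 left out the rises numbered 13 and 11 as well, and the first of these p became 0.0239. Of 6 cholinergic and motor neuron genes 5 rose, with the choline transporter Slc5a7 (1261 ± 107 against 78.0 ± 122 and 152 ± 38.6, with a PVN mean of 23.6 without PVN array 3), the acetylcholine-making enzyme Chat (3.84, 414 ± 69.4 in RVLM), Prph (2.65) and Ret (1.02, named after its value was seen) beside Calca. Without the array labelled PVN replicate 3 Chat lay under the filter and 4 rose. That list had adjusted p = 0.000308, and adjusted p = 0.0154 with an estimated correlation. Of 12 astrocyte markers 6 rose, such as Glul (1.19) and Aldoc (0.87), and the transporter Slc1a3 fell by 0.56. Its camera adjusted p was 0.0254, and adjusted p = 0.653 with an estimated correlation, and quantile normalization also ended the call. Fgfr3 (0.59), one of the 6, and Slc1a3 lost their calls when a gene was the mean of its kept probe sets.

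Of 13 magnocellular genes 9 fell, with the calcium-binding protein gene Calb1 (−3.71) beside Oxt, Avp and Pdyn (adjusted p = 5.54e-06, and adjusted p = 0.0154 with an estimated correlation). Of 7 genes of neighbouring cells 5 fell, Pmch (−3.21), Hcrt (−2.16), Npvf (−1.97), Calb2 (−1.72) and Tcf7l2 (−0.70, named after its value was seen). The list had adjusted p = 0.0254, and adjusted p = 0.0865 with an estimated correlation. The call ended without PVN array 4 (adjusted p = 0.0531), with values as deposited or quantile normalized, and with no filter or one at the 60th percentile. Of 8 pituicyte genes, several of which the hypothalamus also expresses, Vim (−2.76), Lhx2 (−1.90), Nkx2-1 (−1.07), Col25a1 (−1.07) and Sox3 (−0.78) fell and the myelin gene Cldn11 rose by 2.03, with Col25a1 and Sox3 named after their values were seen. Its adjusted p was 0.0473, and adjusted p = 0.158 with an estimated correlation. The call ended without PVN array 3 or 4 or RVLM array 3 or 4 (adjusted p 0.0512 to 0.0544), with either pseudocount, with values as deposited or quantile normalized, and with a filter at the 60th percentile.

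The remaining lists were not called in RVLM. Of 15 glutamate genes 5 rose, such as Grik4 (1.85), Grm3 (1.62) and Gria4 (1.56), with Gria3 (0.91) and Grm4 (0.72), the last named after its value was seen, and 6 fell (list adjusted p = 0.395). Of 16 GABA and glycine genes 5 rose, the glycine receptor subunit Glrb (1.62), Slc32a1 (0.86), Gabrg1 (0.72), Gabra2 (0.54) and Slc6a9 (0.44), and 3 fell, Gabbr1 (−0.78), Gabrb1 (−0.57) and Gabrb2 (−0.56) (list adjusted p = 0.373). Gabra2, Slc6a9, Gabrb1 and Gabrb2 were named after their values were seen, and Gabbr1 lost its call when a gene was the mean of its kept probe sets. Of 8 parvocellular genes Penk (1.93) and Tac1 (1.5), the genes of enkephalin and substance P, rose and Trh (−2.85), Arnt2 (−0.94) and Ntng1 (−0.89, named after its value was seen) fell (list adjusted p = 0.959), with Nr3c1 (0.20), named likewise, rising over the list alone. Of 4 catecholamine genes Slc18a2 rose by 1.05 and Th fell by 1.38, with 122 ± 11.8 in RVLM (list adjusted p = 0.959). Of 14 microglial markers C1qc (−0.65), Fcer1g (−0.62), C1qb (−0.61), Csf1r (−0.55) and Tyrobp (−0.42) fell and P2ry12 (0.66) rose, with Csf1r and Tyrobp named after their values were seen (list adjusted p = 0.292). Of 17 endothelial and mural markers Flt1 (0.57) and Slco1c1 (0.32) rose and Vwf (−1.78), Myh11 (−1.27), Pdgfrb (−0.97), Tie1 (−0.66) and Pecam1 (−0.43) fell, those beyond the 4 largest in size named after their values were seen (list adjusted p = 0.951).

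Of 11 choroid plexus and meningeal markers 7 fell, with Igf2 (−2.07), Col1a2 (−1.94) and Col3a1 (−1.72) the largest, and the list had adjusted p = 0.0543. It was called without PVN array 1, 2, 3 or 5 or SON array 4 (adjusted p 0.0110 to 0.0411). With an estimated correlation adjusted p was 0.711, and 0.460 without PVN array 3. With PVN array 3 left out, 9 genes of this list fell and 1 rose, and Col1a2 had −1.36. Pituitary lists had calls in both directions, with Drd2 (0.92) and Trhr (1.12) higher and Pam (−1.73), Gh1 (−1.53) and Ghrhr (−0.85) lower, and list adjusted p = 0.959 for 7 melanotroph and for 7 anterior pituitary genes. A further melanotroph gene, Cpe (0.28, adjusted p = 0.0254), lost its call without SON array 2 or RVLM array 1 or 5 (adjusted p 0.0539 to 0.0862), and Gh1 lost its call with a pseudocount of 16 or 64. None of 3 red blood cell genes was called by limma (list adjusted p = 0.921), where 10364 of all probe sets had an unadjusted p under 0.05. Hoxb3, a gene of hindbrain identity, rose by 1.09 (82.4 ± 13.3 against 43.5 ± 18.5 and 41.1 ± 7.33), and Gata2 rose by 0.54, each the 1 tested member of its list. Without PVN array 3 there were 8 rises in the astrocyte list and 4 falls in the list of neighbouring cells, 6 falls of microglial, 4 of endothelial, 3 of anterior pituitary and 2 of melanotroph genes, and 0 falls of pan-neuronal markers, and the other lists kept their counts except as stated. Counts adjusted over the list alone differed from those over all genes only in the 3 lists for which this is said.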

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

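The tests of whether the array labelled PVN replicate 3 resembles RNA from outside the PVN or from WKY rats were chosen after its values had been seen, while the test of its RNA quality was written before. An array was listed when its gap to the nearest other array of its group was larger than Dixon's test allows at the 95% level. Of 512 tests 51 met this, where chance gives about 1 in 20. Of these, 27 fell on the array labelled PVN replicate 3, 24 of them in genes, of 138 gene tests in the PVN. Genes on all other arrays gave 21, of 483 gene tests in all, which is no more than chance gives. The tests of genes used log2 values after the median shift, and the values printed are deposited intensities.

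The array labelled PVN replicate 3 stood apart in 24 genes. It was higher than the other PVN arrays in 15 of these, with 4749 for Ptgds, 2069 for Igf2, 1466 for Coch, 1326 for Col1a2, 1152 for Ogn, 852 for Mgp, 601 for Col3a1, 467 for Vwf, 347 for Myh11, 336 for Lum, 128 for Aplnr, 113 for Mrc1, 113 for Cemip, 1787 for Vim and 177 for Grm3. It was lower in the peptide and granule genes Cartpt (995), Scg2 (802), Pmch (259), Sst (143), Trh (138) and Crh (38.1), and in Hoxb3 (16) and Tbx19 (15.6). Folr1, on the same list of choroid plexus and meningeal markers as Ptgds and Lum, was lower as well, at 30.2 (136 to 187 on the other PVN arrays). Its Gapdh 3' over 5' signal ratio was 3.33 and its actin ratio 7.01, and the mean log2 signal of its hybridisation controls was 9.23, each above those of the other PVN arrays. Its Ephx2, called higher in SHR RVLM, was 19.9, where the other 18 SHR arrays had 95.8 to 147 and the WKY arrays 3.12 to 21.1. Zfp597 was 26.7 (237 to 292 on the other PVN arrays, mean 63.1 in WKY RVLM) and RT1-CE16 53.6 (177 to 206, and 30.5), while Fry was 613 (724 to 762, and 178), Pxmp4 91.1 (104 to 124, and 30.2), Septin5 280 (182 to 250, and 47.3) and Tstd1 52.9 (30.2 to 74.5, and 148), all 6 chosen after their values were seen.

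If RNA of tissue outside the PVN were in the pool, the array should move towards the SON, where meningeal markers were higher, and over 3905 probe sets its median position was 0.706 on a scale from 0 for the other PVN arrays to 1 for the SON arrays, where the other PVN arrays lay between −0.16 and 0.07, or at 0.0878 to 0.233 when left out of the choice of probe sets. The value restates in large part that the array correlated better with SON (0.936) than with its own group (0.912), which was known beforehand, and does not name the tissue. Degraded RNA would raise the 3' over 5' ratio, and 3.33 for Gapdh lies above the 1.07 to 1.43 of the other 18 SHR arrays, so it may also be part of the pattern. RNA from WKY rats could give the low Ephx2, Zfp597 and RT1-CE16 and the high Elavl1, Kcnd2, Mylk, Hmces and Prss35. It could not give the levels of Fry, Pxmp4, Septin5, Tstd1, Chi3l1 and Gucy1a1 if the RVLM differences held in PVN. These genes were picked after their values were seen and are no tally of the strain calls. The slope of the array on the strain difference over 66 probe sets was 0.427 against SON (0.0324 to 0.0838 for the other PVN arrays) and 0.369 against the other PVN arrays (−0.03 to 0.05 for other SHR arrays against their own groups). With no WKY array of the PVN, RNA from WKY rats cannot be told apart from another source. No biological explanation was tested, since the design gives this array no other group.

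On other arrays some genes at low intensity stood apart: Cd36 at 11 on SHR RVLM array 2 and 0.767 on WKY RVLM array 4, Cga at 4.55 on PVN array 4, Grm3 at 9.54 on NIL array 4, Npvf at 1.43 on SHR RVLM array 2, and Spp1 at 9.50 on PVN array 4. On the SON arrays these were Col25a1 at 168, Agt at 2903 and Slc17a6 at 576 on array 1, Mobp at 834, Opalin at 196 and Ttr at 91.6 on array 2, and Gabre at 21.7 and Hcrt at 15.3 on array 4. On the NIL arrays these were Adh1c at 2326 on array 3, Cartpt at 148 on array 2 and Th at 43.7 on array 4. The remaining ones were Septin5 at 36.9 on WKY RVLM array 5, Tcf7l2 at 171 on PVN array 2, Gria4 at 53.5 on PVN array 4, and Avp at 4200 on PVN array 5, which was set apart only after the median shift. Among whole-array measures, NIL array 3 had a mean log2 signal of its hybridisation controls of 9.19, NIL array 4 a Spearman correlation of 0.956 with its group, and SON array 4 an actin ratio of 3.86.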

How the results depend on the processing

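Leaving out each array in the list tests, and each count without the array labelled PVN replicate 3, were chosen after the data had been seen. The strain calls numbered 214 to 347 probe sets over the processing alternatives and 212 to 283 with each array left out in turn (102 to 136 genes), against 295 with all arrays. The calls for NIL against the nuclei numbered 9804 to 11243 and those for RVLM 8409 to 9924 with each array left out. For PVN against SON the count was 1616 to 3905 probe sets and 1007 to 2440 genes with each array left out, lowest without SON array 3 and highest without PVN array 3. It was 4618 probe sets and 2974 genes with arrayWeights, which lowers the weight of arrays that stand apart, and 1386 probe sets and 849 genes when the PVN and SON arrays were fitted alone, with fewer arrays to estimate the spread. The median of all RVLM differences was −0.03 and became −0.10 with values as deposited.

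List calls depended most on the correlation assumed between genes. With an estimated correlation, 0 strain lists, 2 lists of PVN against SON, 6 of NIL and 2 of RVLM were called by camera of limma, against 2, 6, 12 and 7. For the strain lists 3 had an unadjusted p under 0.05 with the preset correlation. With quantile normalization 4 RVLM lists were called, and the cause was not tested. With each array left out, 0 to 3 strain lists, 4 to 9 lists of PVN against SON, 12 to 13 of NIL and 5 to 8 of RVLM were called, and 0 strain lists were called without SHR RVLM array 2 or without WKY RVLM array 2.

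Of the named genes called, 21 of 28 in the strain comparison, 35 of 49 for PVN against SON, 71 of 73 for NIL and 62 of 67 for RVLM kept their calls and direction under every alternative run. An alternative was not run for a gene whose probe set then lay under the filter, so these counts leave out losses to the filter. The glutamate receptor gene Grm8 reversed: it was −2.72 in NIL (adjusted p = 2.53e-08) on its brightest probe set and 1.52 (adjusted p = 1.41e-05) as the mean of its kept probe sets, because its other kept probe set had the opposite sign. With the replicate block, that is, the replicate number as a term, the counts were 245 probe sets for the strain, 3018 for PVN against SON, 10695 for NIL and 9083 for RVLM, and it ended the calls of Abat between the strains and of Gch1, Ptprc, Slc5a7 and the microglia and neighbouring-gene lists for PVN against SON. Arrays with the same number correlated at −0.09 to 0.11 between the strains and at 0.08 to 0.17 between PVN and SON, and 2 arrays in each case correlated best with their own number. Between NIL and SON 3 of 4 arrays did so, at correlations of 0.004 to 0.034, between NIL and PVN 1 of 5, and between RVLM and either nucleus 0. The numbers were not taken to pair samples, though shared rats cannot be excluded. Changes of 0.5 on the log2 scale were called in 29.9% and 31.8% of the simulated cases. Detection calls were not used here, so how far signal over background limits the dim genes was not measured.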

Other observations

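The tests of the 2 list calls without SHR RVLM array 2 were chosen after the result had been seen. Hormone genes of the anterior pituitary list varied widely between the NIL pools. Gh1 ranged from 693 to 6068 and Tshb from 52.9 to 2577 over the 5 NIL arrays, and prolactin (Prl), which the filter removed, from 190 to 3677. Pomc, the precursor made by melanotrophs, had 868 ± 254 (SD, n = 5). The highest Gh1, Tshb and Prl were on NIL array 2, the 1 pool labelled 10 to 12 weeks old where all others were 10 to 13. NIL array 1, labelled 10 to 13 weeks, had 5471 for Gh1, 2586 for Prl and 298 for Tshb, and 1 pool cannot tie the spread to age. Pomc, Prl, Rax, Slc18a3 and Tagln lay under the filter although bright in 1 structure, and were chosen after their values were seen. Tagln had 229 in SON and at most 91.8 as a mean elsewhere. Rax, a transcription factor of pituicytes, had 408 in NIL and at most 11 as a mean elsewhere, and the vesicular acetylcholine transporter Slc18a3 had 267 in SHR RVLM and at most 28.0. The angiotensin receptor gene Agtr1a had 68.8 ± 31.6 in PVN, 22.4 ± 2.53 in SON (n = 4) and 36.8 ± 4.21 in NIL, against 14.7 ± 2.15 in SHR RVLM. On PVN array 3 it was 19.4 (60.7 to 104 on the other PVN arrays), and the PVN had 81.2 ± 17.7 without that array. Sim1, a transcription factor of PVN and SON development, had 77.3 ± 14.3 in PVN and 96.8 ± 20.3 in SON and means of at most 6.70 elsewhere.

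In the RVLM, Sgk1 was 438 ± 158 in SHR and 214 ± 19.6 in WKY (log2 difference 0.94, limma adjusted p = 0.00493). Cdkn1a was 127 ± 16.6 and 61.6 ± 5.53 (1.01, limma adjusted p = 8.82e-05). Per1 lay under the filter and was not tested between the strains, with 26.9 ± 15.6 and 9.48 ± 4.59. Its groups overlapped, with 9.30 to 52.0 in SHR and 5.00 to 17.0 in WKY. All 3 genes are induced by glucocorticoids and were chosen after their values were seen. A shared glucocorticoid response could raise other induced genes, and this was tested on 15 further ones. The camera p was 0.158 (mean log2 difference 0.01), with 0 genes called higher and Mt2A called lower at −0.61, so the wider list did not rise, though a p above the threshold does not show that it was unaffected. By limma 1801 of all probe sets had an unadjusted p under 0.05 in that comparison.

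The strain calls may in part reflect sequence variants under single probe sets, since the array was designed on reference sequence. For 65 called genes with other kept probe sets, the median difference of the partners was 0.304 of that of the called probe set (95% interval 0.097 to 0.447). In PVN against SON, where all arrays were labelled SHR, matched draws gave 0.572 (0.485 to 0.658). That comparison included the PVN array set apart above, in which RNA from WKY rats could not be told apart from another source. The draws were not repeated without that array. The lower ratio is consistent with variants under some probe sets, and true differences in expression or splicing stay open, as no probe sequence of either strain was used here. For Pxmp4 and Adpgk the other probe set differed in the same direction, which argues against it for these genes alone. That of Gucy1a1 did not pass at an unadjusted p under 0.05 by limma in the same direction. Ephx2, Tstd1, RT1-CE16, Zfp597, Fry and Grifin had no other kept probe set, so a variant could not be checked for them.

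Called strain genes also lay side by side more often than expected by chance: 8 of 146 placed genes had a called gene as their nearest measured neighbour, against a median of 2 in 1000 shuffles, of which 8 gave as many. The pairs were Setd1b with Rhof, RT1-CE16 with RT1-CE12, RT1-DMa with RT1-DMb, and Birc7 with Nkain4, and the RT1-CE pair differed in opposite directions (2.34 and −0.54). Both genes of each pair entered the count of 8. The RT1-CE and RT1-DM pairs are antigen presentation genes, and probes of RT1-CE genes can read related transcripts. The shuffles were not repeated without these pairs, so a grouping of strain calls beyond the RT1 genes is not shown.

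The lower respiratory chain and ribosomal lists in SHR RVLM likely rest on 1 array. Without SHR RVLM array 2 the mean list differences were 0.0908 and 0.0522 of those with all arrays, and that array had mean list scores of −0.64 and −0.81 where the other RVLM arrays lay between −0.13 and 0.28. No biological explanation was tested, since the labels do not set that pool apart from the other SHR pools.

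The number of calls was set against that of other splits of the arrays, which cannot test a batch shared by a whole group. Of 100 splits of the RVLM arrays, 1 gave as many as the real 295 probe sets, the real one itself, and the highest other gave 1. A chance split of these arrays is therefore an unlikely reason for the strain calls. In the structure comparisons other splits mix tissues within a group, which widens the spread. A high rank of the real count was thus close to given beforehand, and no conclusion is drawn from it. For NIL and RVLM against the nuclei 1 of 100 splits each, the real one, gave 10612 and 9264, and the highest others gave 5190 and 4283. For PVN against SON 2 of 100 gave as many as the real 2740, and the highest other gave 3345. That split put the array labelled PVN replicate 3 with the 4 SON arrays against the other 4 PVN arrays, which points to that array as a structure in the samples.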
